A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

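Total RNA of S. cerevisiae in the W303 background was extracted with hot phenol from cells grown to mid-log phase in rich medium (YPD) at 30 °C, depleted of rRNA and made into stranded libraries, per the labels' protocols. The strain is MATα with the tor1-1 allele, an FPR1 deletion and RPL13A fused to FKBP12, and the tagged strain adds Dbp2-FRB-GFP, per the labels. The tag is given in the source name and not in the genotype field of the tagged samples. The design text states 2 biological replicates per condition and a strand-specific protocol. Reads were trimmed with Trim Galore, aligned with HISAT2 2.2.0 to R64 and counted with featureCounts 2.0.0, and DESeq2 was used, per the submitters' processing notes; the strand setting of the counting is not given in the sources used here.

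The authors deposited a table of signal values, read densities per nucleotide, for 10891 features (10799 yeast features and 92 ERCC spike-in RNAs), with a column for each of the 8 libraries and a mean per group, per the file headers. The values were found to be whole reads divided by a feature length and by 1 factor per library, and these factors equal median-of-ratios factors of the 92 spike-ins. For each feature the shortest length up to 40000 nt was taken that makes its reads whole within 0.01 reads in all libraries, or the reference length where that is a multiple of it, so the reads of some features are too low by a common factor. All positive values (100.0%) came out whole, partly by construction because the length was chosen for it, and 778 of 5900 protein-coding genes were whole at the coding length of the reference. The recovered reads describe depth (22523197 to 27500261 yeast reads per library) and serve 1 added alternative, and no count model was the main test. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom of 5.01 to 20.1 over features with at least 20 reads), so none looked like a repeat of another library.

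The main test was limma 3.58.1 (R 4.3.3) on log2(density + 0.00721), the pseudocount being the 5th percentile of positive values, with a trend of the prior on the mean and a shared spread over all 8 libraries (4 residual and 18.0 prior degrees of freedom). Features with a mean density under 0.0133, the 10th percentile, and the spike-ins were left out, which left 9656 features. The 5 comparisons were tag without rapamycin, strains with rapamycin, rapamycin in each strain and their interaction, two-sided, with Benjamini-Hochberg adjustment over all features tested at 0.05. An exact permutation test of 2 against 2 libraries has 6 arrangements and cannot reach that threshold, so no single-gene permutation test was run. Transcript classes and gene lists were tested against the other features with camera (preset correlation of 0.01), again with an estimated correlation. Fry tested whether a set moved on balance one way, without a comparison with other features. Fold changes are on the log2(density + pseudocount) scale and understate the change of low genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for loading, context tests and plots.

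The gene lists were ribosomal proteins, ribosome biogenesis, nitrogen-catabolite genes, the retrograde pathway, Gcn4 targets, stress genes, galactose, hexose transport, phosphate, iron, glucose-repressed, sulfur and methionine, RNA decay and termination, DEAD-box helicases, mRNP export, histones, mitochondrial DNA, α-specific genes, genes of the other mating type and genotype markers. The lists, groups, tests, alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names DBP2 and genotype markers, called features among the 10 highest and 10 lowest fold changes whose groups do not overlap, the 5 lowest p where fewer than 5 were called, up to 4 called members of a list and up to 5 features of a noncoding class by lowest p; MF(ALPHA)1 and STE3 were named after their values were seen.

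Alternatives were another pseudocount, filter, scaling (protein-coding features, snoRNAs, quantiles), spread, trend, replicate block and effect threshold, and leaving out each library in turn, where the lone library of a group is assumed to vary like the other groups. Added after the data were seen were voom on the recovered reads, a minimum of 50 mean reads and camera with an estimated correlation after scaling to protein-coding features. A count test with another tool was listed as an alternative and not run because the table holds no counts.

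On simulated data for the strain comparison with rapamycin (9569 features, 5 draws, with library-wide shifts), 49.1, 70.1 and 91.0% of features changed 1.5-, 2- and 4-fold were recovered, and 21.6% of calls were false. For the interaction 3.37, 56.1 and 84.3% were recovered and 18.6% of calls were false. Without library-wide shifts (9568 features) 7.26 and 5.03% of calls were false. Features under 50 reads made up 99.5 and 100% of the false calls with such shifts and 75 and 51.5% without. Each draw changed 200 features and shifted a list of 40, with 1 dispersion of 0.00066 for all features. In the data 7009 of 9656 features were called between the treated strains, so these shares need not hold there. Features that may share reads (overlapping genes, HSP12 with NUT0227, paralogs such as CUP1, PHO11 and PHO12, ASP3 and histone copies) are uncertain. How the counting split such reads is not given in the sources used here. Coordinates are from the R64 reference annotation, and XUTs, CUTs and NUTs have none here. Stable unannotated transcripts, tRNAs and rRNAs were not analysed here.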

Results

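The series measured RNA by stranded sequencing of rRNA-depleted total RNA from the budding yeast Saccharomyces cerevisiae. The 8 libraries fell into 4 groups of 2 biological replicates: a parental anchor-away strain without rapamycin, the parental strain with rapamycin at 1 µg/mL for 1 h, and a strain in which the DEAD-box RNA helicase Dbp2 carries an FRB-GFP tag, without and with the same treatment. In an anchor-away strain rapamycin bridges an FRB-tagged nuclear protein to a ribosomal protein fused to FKBP12, which carries it out of the nucleus as ribosomal subunits are exported. The labels give the strains a TOR1 allele that does not respond to rapamycin and a deletion of FPR1. The series title asks whether long noncoding RNAs degraded by the cytoplasmic exonuclease Xrn1 (XUTs, Xrn1-sensitive unstable transcripts) depend on nuclear Dbp2. The file also held cryptic unstable transcripts (CUTs, degraded by the nuclear exosome), Nrd1-unterminated transcripts (NUTs), snoRNAs and protein-coding genes. The libraries held 22523197 to 27500261 yeast reads and 747342 to 1267031 reads of the 92 ERCC spike-in RNAs, which made up 2.93 to 4.44% of a library. Values are read densities that the authors scaled to the spike-ins, given as mean ± SD (n = 2). Fold changes are log2 ± standard error on the log2(density + pseudocount) scale, which understates the change of low genes.

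DBP2 (YNL112W, R64 chromosome XIV 413639–416281, plus strand, 2 coding parts) was read in every library, with 6376 to 10450 reads. Its density was 2.52 ± 0.131 in parental and 3.04 ± 0.0127 in Dbp2-FRB-GFP cells without rapamycin, and 2.44 ± 0.213 and 3.60 ± 1.04 with it. The tag acts on the position of the protein, so the RNA level does not test the depletion. The upstream neighbour RPC19, a subunit of RNA polymerases I and III, and the downstream neighbour CYB5, cytochrome b5, rose in the tagged strain without rapamycin by 0.41 ± 0.16 and 0.46 ± 0.16 (limma adjusted p = 0.0387 and 0.0224). Both calls were lost without parental untreated replicate 1 (0.252 and 0.249), without Dbp2-FRB-GFP untreated replicate 1 (0.141 and 0.0801) or without its replicate 2 (0.0981 and 0.0632), and both also ended after scaling to protein-coding features (0.2 and 0.102). After scaling to snoRNAs both values turned negative (−0.24 and −0.20). LEU2, a selection marker of the background, fell by 0.45 ± 0.14 (adjusted p = 0.0113), a call lost without parental untreated replicate 2 (0.0869) or Dbp2-FRB-GFP untreated replicate 2 (0.126). FPR1, deleted in these strains per the labels, had 74 to 122 reads in the 8 libraries, with densities of 0.118 ± 0.0215 in parental and 0.143 ± 0.0106 in tagged cells without rapamycin and 0.132 ± 0.00456 and 0.115 ± 0.00541 with it. The file does not show where in the gene these reads fall, so they neither show nor rule out the deletion.

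The comparison of tagged with parental cells without rapamycin asks how the 2 strains differ before the drug; it holds the effect of the tag and any other difference between the strains. The α-factor gene MF(ALPHA)2 (chromosome VII 344791–345153, minus strand) fell from 26.3 ± 0.837 to 2.63 ± 0.199, by 3.32 ± 0.13 (limma adjusted p = 7e-14). The repressible acid phosphatase gene PHO5 (chromosome II 429548–430951, minus strand) fell from 10.01 ± 0.809 to 1.97 ± 0.212, by 2.35 ± 0.15 (adjusted p = 1.16e-10), and HO, the mating-type switching endonuclease, fell by 2.36 ± 0.18. The glutathione transferase and oxidoreductase genes GTT2 (−2.08 ± 0.16), OYE3 (−2.02 ± 0.19) and YNL134C (−2.11 ± 0.14) fell too. Among the features that rose most were the small open reading frames YMR230W-A (0.0912 ± 0.0286 to 1.33 ± 0.21; 3.79 ± 0.20, adjusted p = 1.24e-11) and YBR032W (3.10 ± 0.21), which lie 126 and 264 nt behind the ribosomal protein genes RPS10B and RPL4A on the same strand, and YLR366W (2.78 ± 0.16). The noncoding CUT567 rose from 2.74 ± 0.418 to 20.6 ± 0.207 (2.91 ± 0.13, adjusted p = 1.07e-12), CUT122 by 3.58 ± 0.36 and XUT0506 by 3.14 ± 0.23. HSP12, a membrane stress protein gene, rose by 3.76 ± 0.48. Its parental replicates held 432 and 73 reads. NUT0227 had nearly the same value, so the 2 features probably share reads, which the file does not show directly. The near-identical metallothionein copies CUP1-1 (5.36 ± 0.63) and CUP1-2 (2.91 ± 0.21) also rose, but reads of these copies cannot be assigned with certainty, and CUP1-1 was 3.48 without parental untreated replicate 1, which held 5 of its reads against 71 in replicate 2.

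By transcript class, 2016 protein-coding features were higher and 198 lower of 6072 tested, with a median log2 fold change of 0.26. Of 1461 XUTs 787 were higher and 41 lower (median 0.54), led by XUT0696 (2.34 ± 0.17, adjusted p = 1.4e-09) among those with the lowest p. Of 828 CUTs 637 were higher and 2 lower (median 0.83), of 1189 NUTs 696 were higher and 22 lower (0.58), of 76 snoRNAs 67 were higher and 3 lower (0.64), and of 25 mitochondrial features 13 were higher and 0 lower. Of the XUTs 850 were called when adjusted over the list alone. The snoRNAs snR52 (2.70 ± 0.13), snR78 (2.26 ± 0.13), snR56 (1.83 ± 0.13) and snR44 (1.56 ± 0.12) were among the risers. snR44 lies within RPS22B, which rose by 1.61 ± 0.13, and the file does not show whether the 2 share reads. The level of a class against the spike-ins, relative to its geometric mean over the 8 libraries, went from 0.846 ± 0.094 to 1.01 ± 0.029 for protein-coding features, from 0.742 ± 0.067 to 1.17 ± 0.042 for XUTs and from 0.662 ± 0.046 to 1.31 ± 0.024 for CUTs. Against all other features, camera called CUTs (adjusted p = 1.3e-13), snoRNAs (7.4e-12), NUTs (0.0035) and XUTs (0.029) higher and protein-coding features lower (6.6e-09). With an estimated correlation these adjusted p were 0.175, 0.345, 0.683, 0.683 and 0.683. By fry, which asks whether a set moved on balance one way and makes no comparison with other features, XUTs, CUTs, NUTs, snoRNAs and mitochondrial features rose (adjusted p = 0.000426 to 0.00194) and protein-coding features were not called (0.0747). After scaling to snoRNAs the medians of snoRNAs and protein-coding features turned negative (−0.01 and −0.38), and after quantile normalization those of XUTs and protein-coding features (−0.03 and −0.06).

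**Figure D1:**
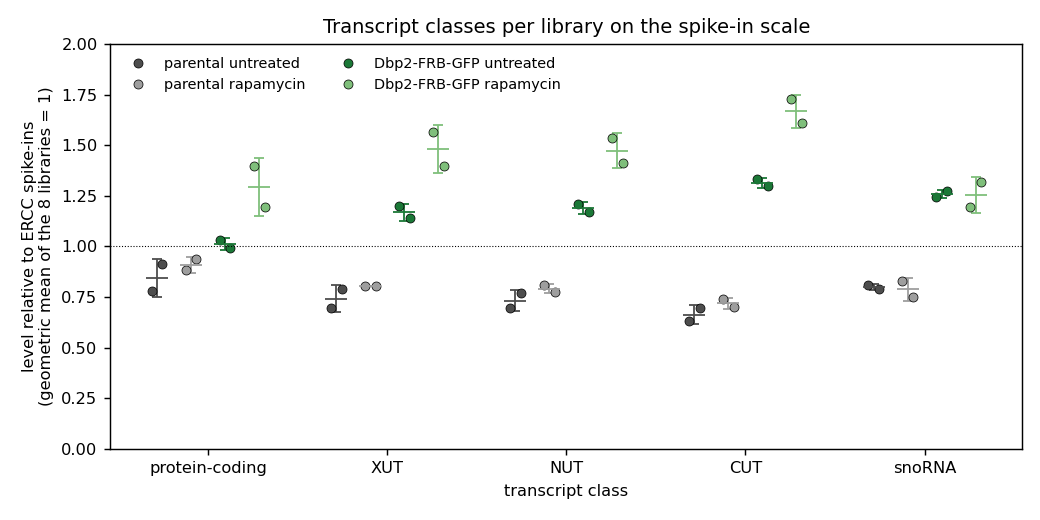
Level of each transcript class relative to the ERCC spike-ins in the 4 groups (vertical axis, geometric mean of the 8 libraries = 1), with each library as a point and the mean ± SD (n = 2) as a bar. CUTs were at 0.662 in parental and 1.31 in Dbp2-FRB-GFP cells without rapamycin, while protein-coding features were at 0.846 and 1.01; scaled to snoRNAs, the protein-coding difference turned negative.

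Methionine and sulfur assimilation genes were lower as a group: 13 of 15 fell and 0 rose, including the methionine synthase MET6 (11.0 ± 1.18 to 4.41 ± 0.48; −1.32 ± 0.14), MET17 (−1.25 ± 0.13), MET2 (−1.33 ± 0.16) and STR3 (−1.18 ± 0.19). Of 16 phosphate-starvation genes 11 fell and 1 rose, among them GIT1 (−1.58 ± 0.17) and the near-identical phosphatase copies PHO12 (−1.88 ± 0.17) and PHO11 (−1.75 ± 0.18). Of 4 α-specific genes MF(ALPHA)2 and SAG1 (−0.57 ± 0.14) fell. The SAG1 call was lost without Dbp2-FRB-GFP untreated replicate 2 (0.0537), while MF(ALPHA)1 (0.21, adjusted p = 0.196) and STE3 (−0.12, 0.485) were not called on the spike-in scale. MF(ALPHA)1 was called lower after scaling to snoRNAs (−0.45, 0.0343) and after quantile normalization (−0.20, 0.0263), and STE3 after these (−0.78, 0.00256 and −0.33, 0.00128) and after scaling to protein-coding features (−0.38, 0.000292). Of 6 genes specific to the other mating type 4 rose (median 0.69), among them STE2 (0.58 ± 0.17) and MFA1 (1.17 ± 0.45, 9 and 10 against 14 and 28 reads). STE2 was lost without parental untreated replicate 1 (0.086) or Dbp2-FRB-GFP untreated replicate 1 (0.0766) and was −0.0199 after scaling to snoRNAs and 0.01 after quantile normalization. MFA1 was lost without parental untreated replicate 1 (value 0.94) or 2 (1.39) and was 0.68 without Dbp2-FRB-GFP untreated replicate 2. Its call also ended after scaling to protein-coding features (0.94, limma adjusted p = 0.341) and after quantile normalization (0.61, 0.522). The same held with a pseudocount at the 1st percentile (1.24, 0.132) and, at an unchanged value, without a filter (0.111) or a trend (0.106). Nitrogen-catabolite genes were mixed, 4 higher and 7 lower of 25, with DAL3 at −0.96 ± 0.15, as were Gcn4 targets, 4 and 4 of 18, with SNO1 at −1.16 ± 0.18 and HIS4 at −0.92 ± 0.14, and retrograde-pathway genes, 2 and 2 of 7. A total of 13 sulfur, 13 phosphate, 11 nitrogen, 8 Gcn4 and 4 retrograde genes were called when adjusted over the list alone. Camera called these lists lower (sulfur 1.5e-25, phosphate 4.3e-22, nitrogen 1.3e-06, Gcn4 4.6e-06, α-specific 4.6e-06, retrograde 0.041), with adjusted p of 0.264, 0.264, 0.888, 0.888, 0.264 and 0.964 with an estimated correlation. Apart from histone and iron genes, it did not set the other lists apart from other features (0.359 to 0.816), stress (0.668) and glucose-repressed genes (0.359) among them. The sulfur and phosphate medians (−0.77 and −0.55) stayed negative under each scaling. Of the lists, fry called sulfur (0.0112), phosphate (0.0288) and α-specific genes (0.00579) lower and galactose, hexose transport, glucose-repressed, histone and mitochondrial DNA genes and those of the other mating type higher (0.00579 to 0.0322), and did not call the others (0.18 to 0.803).

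Histone genes rose in 9 of 10 (median 0.71), with HTB2 at 0.95 ± 0.13, HHF1 at 0.88 ± 0.13 and HHT1 at 0.76 ± 0.13 (camera adjusted p = 0.0018, and adjusted p = 0.964 with an estimated correlation). HHF1 and HHT1 have near-identical copies, and after scaling to snoRNAs the 3 genes were no longer called and stood at 0.30, 0.23 and 0.10. Of 25 stress genes 13 rose and 0 fell (median 0.54), with hexokinase HXK1 at 1.28, and of 14 glucose-repressed genes 9 rose and 0 fell (median 0.57), with the isocitrate lyase ICL1 at 1.17, the alcohol dehydrogenase ADH2 at 1.16 and CAT2 at 1.01. Of 14 hexose transport genes 7 rose, with HXT7 at 1.39, and of 9 galactose genes 4 rose, with MTH1 at 1.41. These 4 medians turned negative after scaling to snoRNAs (−0.04, −0.01, −0.11 and −0.19), and the galactose median also after quantile normalization (−0.04). Of 137 ribosomal protein genes 64 were higher and 5 lower, with RPL7B at −1.55 ± 0.14. Of 41 ribosome biogenesis genes 13 were higher, of 31 RNA decay and termination genes 7, of 24 DEAD-box helicase genes 5, of 12 mRNP export genes 3 and of 8 mitochondrial DNA genes 5, with 0 lower. Their medians turned negative after scaling to snoRNAs (−0.34, −0.45, −0.45, −0.40, −0.36 and −0.30), and those of ribosome biogenesis, RNA decay and helicase genes also after scaling to protein-coding features (−0.06, −0.07 and −0.02). After quantile normalization the biogenesis and decay medians were −0.02 and −0.08 and that of ribosomal protein genes lay just below 0. NRD1, which binds nascent noncoding RNA for termination, rose from 0.515 ± 0.0504 to 1.08 ± 0.00116 (1.06 ± 0.15), the decapping subunit DCP1 by 0.82 ± 0.15 and the export adaptor YRA1 by 0.67 ± 0.14. After scaling to snoRNAs these 3 and CAT2 were no longer called (NRD1 0.41, DCP1 0.17, YRA1 0.01 and CAT2 0.39). Of 22 iron genes 6 were higher and 2 lower, with a median of 0.06 above 0 but a camera direction below the other features (adjusted p = 0.024, and adjusted p = 0.964 with an estimated correlation); the median was −0.19 after scaling to protein-coding features. Adjusted over the list alone, 72 ribosomal protein, 8 biogenesis, 5 decay, 5 helicase, 2 export, 5 mitochondrial, 9 histone, 13 stress, 9 glucose-repressed, 7 hexose, 4 galactose and 8 iron genes were called, with 2 α-specific genes and 4 of the other mating type.

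In all, limma called 4219 features higher and 266 lower of 9656 at an adjusted p under 0.05, of which 950 and 49 moved at least 2-fold. Scaling to protein-coding features moved the all-feature median from 0.36 to 0.12 and the split to 2712 higher and 1450 lower, scaling to snoRNAs to −0.25 with 650 and 1967, and quantile normalization to −0.02 with 1625 and 1886. For XUTs the splits were 497 and 70, 176 and 153, and 206 and 194, so the size of the excess of higher over lower XUTs rests on the scale. The count of called features was 2733 without parental untreated replicate 1 and 2860 without Dbp2-FRB-GFP untreated replicate 1.

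**Figure D2:**
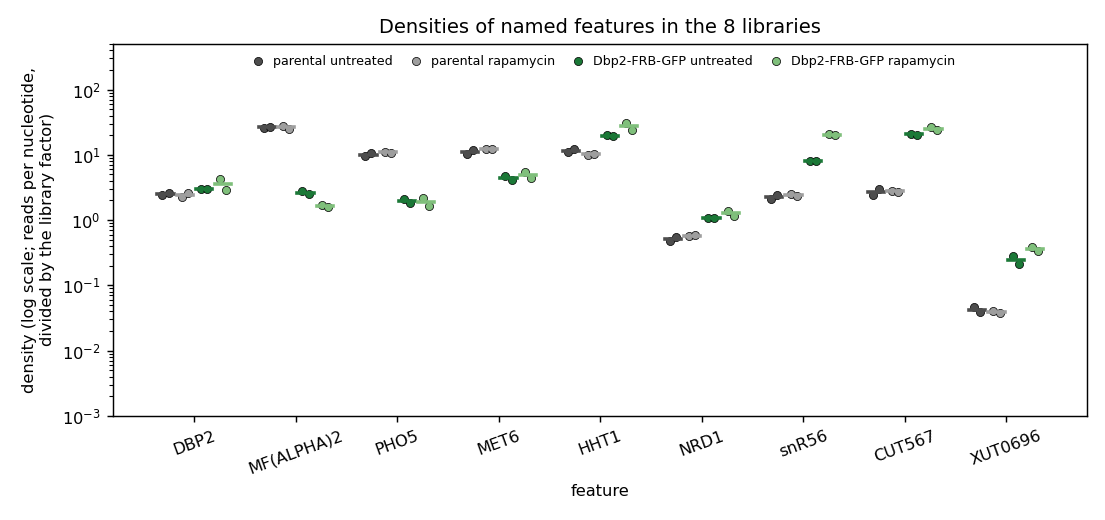
Read density (reads per nt divided by the authors' spike-in factor, log axis) of named features in the 4 groups, each library as a point and the mean as a bar. MF(ALPHA)2 was at 26.3 in parental and 2.63 in Dbp2-FRB-GFP cells without rapamycin, and snR56 was at 8.05 in untreated and 20.3 in treated Dbp2-FRB-GFP cells.

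The comparison of the strains with rapamycin asks how cells treated to draw Dbp2 out of the nucleus differ from treated parental cells. This comparison also holds any effect of the tag, and the depletion itself was not measured here. MF(ALPHA)2 was again lower (−3.99 ± 0.13, limma adjusted p = 1.33e-15), as were PHO5 (−2.53 ± 0.15), HO (−2.35 ± 0.18), GTT2 (−2.29 ± 0.16), YNL134C (−2.24 ± 0.14) and OYE3 (−2.10 ± 0.19). The open reading frame YMR230W-A rose by 5.03 ± 0.20, RRT5 (chromosome VI 222090–222959, minus strand, 298 nt behind the ribosomal protein gene RPL29) by 4.32 ± 0.24 and HSP12 by 4.25 ± 0.48. MFA1, an a-factor gene, rose by 3.70 ± 0.45 from 6 and 0 reads to 34 and 28, and by 2.41 without parental rapamycin replicate 2. DBP2 itself rose by 0.53 ± 0.16 (adjusted p = 0.00592). That call was lost without parental rapamycin replicate 1 (0.0568) or Dbp2-FRB-GFP rapamycin replicate 1 (0.23, adjusted p = 0.186), the value was 0.83 without Dbp2-FRB-GFP rapamycin replicate 2, and it was 0.02 after scaling to protein-coding features and −0.14 after scaling to snoRNAs. CYB5 rose by 0.80 ± 0.16 and RPC19 by 0.75 ± 0.16, the latter by 0.48 without Dbp2-FRB-GFP rapamycin replicate 1. Both were lost after scaling to snoRNAs (0.13 and 0.08), and RPC19 also after scaling to protein-coding features (0.24).

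Of the noncoding classes, 1067 XUTs were higher and 35 lower of 1461 (median 0.75), with XUT0506 at 3.46 ± 0.23, XUT1354 at 3.29 ± 0.21 and XUT0696 at 2.99 ± 0.17, and 1110 were called adjusted over the list alone. Of 828 CUTs 722 were higher and 2 lower (median 1.02), with CUT567 at 3.19 ± 0.13, CUT627 at 3.04 ± 0.16 and CUT866 at 2.91 ± 0.15. Of 1189 NUTs 908 were higher and 20 lower (0.74), of 76 snoRNAs 67 and 2 (0.70), of 25 mitochondrial features 18 and 0, and of 6072 protein-coding features 4018 and 147 (0.50). The snoRNAs snR56 (3.06 ± 0.13), snR52 (2.94 ± 0.13) and snR78 (2.63 ± 0.13) rose, while snR59, which lies within RPL7B, fell by 2.00 ± 0.16 together with RPL7B (−1.83 ± 0.14). RPS22B rose by 1.86 ± 0.13. Camera called CUTs (2.2e-07) and snoRNAs (4.6e-05) higher and protein-coding features lower (0.0031) than other features, with adjusted p of 0.45, 0.85 and 0.863 with an estimated correlation, while XUTs (0.49) and NUTs (0.38) were not called. Fry called all 6 classes higher (0.000166 to 0.0105). After scaling to protein-coding features 518 XUTs were higher and 93 lower and 438 CUTs were higher and 11 lower, and after quantile normalization XUTs split into 249 higher and 230 lower, with XUT and NUT medians of −0.03 and −0.01.

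Sulfur genes fell in 10 of 15, with 0 higher (MET2 −1.57 ± 0.16, MET6 −1.33 ± 0.14, MET17 −1.20 ± 0.13), and phosphate genes fell in 10 and rose in 2 of 16 (PHO12 −1.88 ± 0.17). Histone genes rose in 10 of 10, with HTB2 at 1.45 ± 0.13, HHF1 at 1.41 ± 0.13 and HHT1 at 1.43 ± 0.13 (10.2 ± 0.38 to 27.6 ± 4.74). The sulfur, phosphate and histone medians (−0.81, −0.47 and 1.16) kept their sign under each scaling. Stress genes rose in 22 of 25 (HXK1 1.62, CTT1 1.49, SPI1 1.43) and glucose-repressed genes in 12 of 14 (CAT2 1.45, ICL1 1.43, ADH2 1.40), with 0 lower and medians of 0.73 and 0.83. Among RNA decay and termination genes 18 of 31 rose, with DCP1 at 1.26 ± 0.15 and NRD1 at 1.14 ± 0.15, among helicase genes 17 of 24, with DBP6 at 1.38 ± 0.15, and among export genes 10 of 12, with YRA1 at 1.02 ± 0.14. The medians of the decay and helicase lists turned negative after scaling to protein-coding features or snoRNAs, and that of the export list after scaling to snoRNAs, where NRD1 (0.47) and YRA1 (0.35) were no longer called. After quantile normalization the decay and helicase medians were −0.06 and −0.05. Of the remaining lists, ribosomal protein genes were 96 higher and 3 lower, biogenesis 28 and 0, nitrogen 8 and 8, Gcn4 targets 7 and 3, retrograde 3 and 1, galactose 8 and 0, hexose transport 10 and 0, iron 8 and 1, mitochondrial DNA 7 and 0, α-specific 0 and 2, and genes of the other mating type 5 and 0. After scaling to protein-coding features the ribosomal protein, biogenesis, nitrogen, Gcn4, retrograde and iron medians were −0.02, −0.04, −0.43, −0.43, −0.38 and −0.29, and after scaling to snoRNAs also those of galactose, hexose transport and mitochondrial DNA genes turned negative (−0.01, −0.01 and −0.15). Adjusted over the list alone the counts were 10 sulfur, 12 phosphate, 10 histone, 22 stress, 12 glucose-repressed, 18 decay, 17 helicase and 10 export genes. Camera called sulfur (4.2e-30), phosphate (2.8e-27), nitrogen (3.4e-10), α-specific (2.5e-10), Gcn4 (4.3e-05) and iron (0.0022) genes lower and histones higher (1.3e-04), with adjusted p of 0.164, 0.19, 0.656, 0.164, 0.866, 0.904 and 0.866 with an estimated correlation. It did not set the other lists apart from other features (0.084 to 0.993), among them stress (0.237), glucose-repressed (0.514), decay (0.92), helicase (0.954) and export genes (0.954). Fry called sulfur, phosphate and α-specific genes lower (0.00224 to 0.0286), did not call biogenesis, nitrogen, retrograde, Gcn4 and iron genes (0.0527 to 0.936), and called the other 11 lists higher (0.00224 to 0.0427).

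In all, 6803 features were called higher and 206 lower, of which 1908 and 49 moved at least 2-fold. The split was 2867 and 1807 after scaling to protein-coding features (all-feature median 0.12 against 0.59), 1233 and 1011 after scaling to snoRNAs (−0.04) and 1963 and 2242 after quantile normalization (−0.02). Across features the fold changes of the strain with and without rapamycin, which share no library, correlated at Pearson r = 0.86 and Spearman rho = 0.845; features are not independent replicates. They shared 4079 of the higher calls (2972 from independent lists) and 181 of the lower ones (5.68 from independent lists), and 2 features were called in opposite directions.

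**Figure D3:**
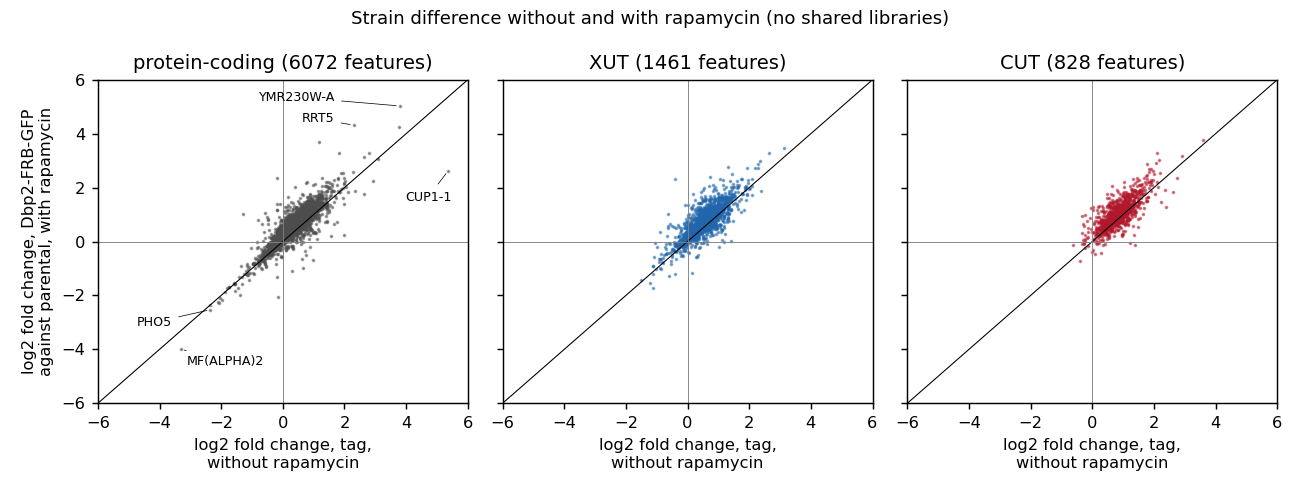
Log2 fold change of Dbp2-FRB-GFP against parental cells without rapamycin (horizontal axis) and with rapamycin (vertical axis) for 6072 protein-coding features, 1461 XUTs and 828 CUTs, 1 point per feature, with the diagonal of equal change. Most XUTs and CUTs lie right of and above 0 on the spike-in scale, but scaled to protein-coding features fewer XUTs were called higher (518 against 1067 with rapamycin).

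The comparison of rapamycin with no rapamycin in parental cells asks what the drug does without a tagged protein. PIR3, a cell wall protein gene (chromosome XI 144401–145378, plus strand), rose from 0.448 ± 0.0259 to 0.845 ± 0.123 (0.90 ± 0.15, limma adjusted p = 0.0151). XUT0992 rose by 1.50 ± 0.23 (0.0136) from 2 and 2 to 10 and 7 reads, and XUT0807 fell by 1.20 ± 0.19 (0.0151) from 11 and 10 to 3 and 3 reads. The allantoate permease gene DAL5 (0.81 ± 0.16, adjusted p = 0.0808) and the vitamin B6 gene SNO1 (0.89 ± 0.18, 0.0808) had the next lowest p but were not called. Of the lists' other members, the vitamin B6 gene SNZ1 (0.73 ± 0.15, 0.0808), the citrate synthase CIT2 (0.63 ± 0.14, 0.0913) and the repressor DAL80 (0.64 ± 0.15, 0.129) were not called either, with features outside the lists ranked between them. Adjusted over the list alone, 5 nitrogen-catabolite, 6 retrograde, 4 Gcn4, 2 mitochondrial DNA genes and 1 gene of the other mating type were called and 0 of the other lists, while over all features limma called 0 of any list. Camera placed the nitrogen (2.3e-08), retrograde (2.2e-08), Gcn4 (9.4e-07) and mitochondrial DNA (0.002) lists higher and ribosomal protein and biogenesis genes (0.016 each) lower than other features, with adjusted p of 0.774, 0.655, 0.774, 0.655, 0.869 and 0.869 with an estimated correlation. The other lists were not called (0.0597 to 0.675).

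Of 9656 features limma called 2 higher and 1 lower, with 528 at an unadjusted p under 0.05 against 482.8 by chance, and voom called 23. It called 0 CUTs (92 at an unadjusted p under 0.05), 0 NUTs, 0 snoRNAs and 0 mitochondrial features, and 8 XUTs when adjusted over the list alone. Camera placed protein-coding (0.015) and mitochondrial features (0.0019) higher and snoRNAs (9e-06) and CUTs (0.046) lower than the rest, with adjusted p of 0.721 to 0.736 with an estimated correlation. Fry called mitochondrial features (0.0463) and mitochondrial DNA genes (0.0402) higher and no other class (0.411 to 0.896) or list (0.167 to 0.94). The level of XUTs was 0.742 ± 0.067 without and 0.804 ± 0.002 with rapamycin. The PIR3 call was lost without parental untreated replicate 1 (0.96, adjusted p = 0.0786) or 2 (0.84, 0.0806) or parental rapamycin replicate 1 (0.75, 0.0717), that of XUT0807 without parental untreated replicate 1 (−1.30, 0.0786) or 2 (−1.11, 0.105), and that of XUT0992 without parental untreated replicate 1 (1.41, 0.117). DAL5, SNO1, SNZ1 and CIT2 were called without any 1 Dbp2-FRB-GFP library (0.00303 to 0.032) and DAL80 without either Dbp2-FRB-GFP rapamycin library (0.025 and 0.0242). DAL5 was also called without parental rapamycin replicate 1 (0.0074), and SNO1 (0.00196) and SNZ1 (0.0492) without its replicate 2. All 5 were called with a filter at the 25th percentile (0.000438 to 0.0167), with voom (5.57e-05 to 0.0262) and with only the groups compared in the fit (0.000526 to 0.0356). Leaving out any 1 library but parental untreated replicates 1 (1 feature) and 2 (8 features) gave 48 to 77 called features, and scaling to protein-coding features, quantile normalization or no filter gave 0. The values changed little after these 2 scalings (PIR3 0.79 and 0.79, XUT0992 1.49 and 1.48, XUT0807 −1.32 and −1.33; adjusted p = 0.129 to 0.353) and not without a filter (0.0829 each). With voom XUT0807 was not called (0.206), and without a trend PIR3 was not called at an unchanged value (0.171).

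The comparison of rapamycin with no rapamycin in Dbp2-FRB-GFP cells asks what followed 1 h of treatment meant to deplete nuclear Dbp2, together with any effect of the drug. The small nucleolar RNA snR56 (chromosome II 88190–88277, plus strand) rose from 8.05 ± 0.136 to 20.3 ± 0.671 (1.33 ± 0.13, limma adjusted p = 6.4e-06), and NUT0013, with a similar number of reads, by 1.31 ± 0.14. RRT5 rose by 1.73 ± 0.24 (0.000445), XUT1468 by 2.02 ± 0.24, the membrane chaperone HSP30 by 1.90 ± 0.26 and CUT732 by 0.98 ± 0.18. MF(ALPHA)2 fell by 0.67 ± 0.13 (0.00708) and ASP3-1, an asparaginase gene with near-identical copies, by 1.15 ± 0.24 (0.0101; 5 to 57 reads over the 8 libraries). DBP2 was not called (0.21 ± 0.16, 0.267).

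Stress genes rose in 12 of 25, with the disaggregase HSP104 at 1.07 ± 0.21, HSP42 at 0.87 ± 0.16 and the trehalose synthase TPS1 at 0.71 ± 0.14. Retrograde genes rose in 6 of 7, with CIT2 at 0.89 ± 0.14 (adjusted p = 0.00117), Gcn4 targets in 8 of 18, with ARG1 at 0.74 ± 0.15, and histone genes in 6 of 10, with HTB2 at 0.53 ± 0.13. Nitrogen-catabolite genes rose in 4 of 25, with DAL80 at 0.69 ± 0.15, ribosomal protein genes in 4 of 137 and biogenesis genes in 3 of 41. Of the other lists galactose, glucose-repressed, RNA decay and mitochondrial DNA genes had 2 higher each, phosphate, iron, sulfur, helicase and export genes 1 each, and hexose transport and the other mating type 0 each, and MF(ALPHA)2 was the single lower call. Adjusted over the list alone the counts were 16 stress, 7 retrograde, 17 Gcn4, 10 histone, 15 nitrogen, 12 decay and 10 export genes, and 0 hexose transport and 0 of the other mating type. Camera called retrograde (1.2e-05), Gcn4 (4.4e-05), stress (0.0033) and histone (0.0049) genes higher, with an adjusted p of 0.904 each with an estimated correlation. It called α-specific (1.3e-09), phosphate (2.6e-04), ribosomal protein (0.017) and hexose transport (0.046) genes lower than other features, with adjusted p of 0.309, 0.904, 0.947 and 0.904 with an estimated correlation, and did not call the others (0.128 to 0.892). Without Dbp2-FRB-GFP untreated replicate 2 the calls of ARG1 (0.69, adjusted p = 0.0836), HSP42 (0.72, 0.0653), TPS1 (0.62, 0.112), HTB2 (0.55, 0.163) and DAL80 (0.72, 0.0752) were lost, with values near those of all libraries. Those of ASP3-1 (−0.89, 0.064), MF(ALPHA)2 (−0.59, 0.058), DAL80 (0.66, 0.067) and HTB2 (0.52, 0.0998) were lost without untreated replicate 1, and that of HTB2 (0.45, 0.1) without rapamycin replicate 1. Without rapamycin replicate 2 HSP104 was 0.60, HSP30 was 1.24, and DBP2 was called (0.51, 0.0134).

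In all, 1322 features were called higher and 14 lower, among them 1029 and 8 protein-coding features, 142 and 2 XUTs, 81 and 2 CUTs, 65 and 2 NUTs, 2 and 0 snoRNAs and 2 and 0 mitochondrial features. Of the XUTs 92 were called when adjusted over the list alone. The level of protein-coding features went from 1.01 ± 0.029 to 1.30 ± 0.144 and that of XUTs from 1.17 ± 0.042 to 1.48 ± 0.119, while snoRNAs were at 1.26 ± 0.021 and 1.26 ± 0.088. Camera called protein-coding features higher (9.9e-12) and snoRNAs (1.3e-21), NUTs (4.1e-07), CUTs (2.7e-05) and XUTs (9.2e-05) lower than other features, with adjusted p of 0.479, 0.295, 0.441, 0.407 and 0.479 with an estimated correlation. By fry each of these classes but snoRNAs (0.476) and the mitochondrial features rose (0.0151 to 0.0443), as did retrograde (0.041) and mitochondrial DNA genes (0.0103), and no other list was called (0.0628 to 0.53). Scaling to protein-coding features left 5 higher and 13 lower features and 0 XUTs (all-feature median −0.01 against 0.32), quantile normalization 2 and 3, and of the features named for this comparison only snR56, NUT0013 and MF(ALPHA)2 stayed called under both. The values of several features whose calls ended stayed of a similar size after scaling to protein-coding features and after quantile normalization: XUT1468 at 1.70 and 1.69 (adjusted p = 0.0534 and 0.0683), HSP30 at 1.55 and 1.57 (0.212 and 0.21), RRT5 at 1.39 and 1.51 (0.106 and 0.0788) and ASP3-1 at −1.28 and −1.47 (0.0827 and 0.0603). Those of HTB2 (0.18 and 0.29), DAL80 (0.35 and 0.41), TPS1 (0.35 and 0.35) and ARG1 (0.39 and 0.40) lost a larger share of their smaller starting values. Apart from ASP3-1, scaling to protein-coding features lowered all these values by about the same log2 amount. This follows from dividing each library by 1 factor, apart from the pseudocount. The larger share lost by smaller values is therefore no separate result. The XUT, CUT, NUT, snoRNA and protein-coding medians were −0.01, −0.02, −0.04, −0.33 and −0.01 after scaling to protein-coding features. Scaling to snoRNAs gave 172 and 13, with 39 and 1 XUTs, and ended the calls of DAL80 (0.0696) and HTB2 (0.12). Without 1 library the count was 352 (Dbp2-FRB-GFP untreated replicate 1), 117 (untreated replicate 2), 258 (rapamycin replicate 1), 4712 (rapamycin replicate 2), 2615 (parental untreated replicate 1) or 2606 (parental untreated replicate 2), and for XUTs 77, 24, 44, 379, 234 and 230.

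The interaction of strain and rapamycin, the test of whether the drug acted differently in the tagged strain, bears most directly on the depletion. It called 4 features: snR56 (1.23 ± 0.18, limma adjusted p = 0.00849), NUT0013 (1.18 ± 0.20, 0.0211) and RRT5 (2.01 ± 0.35, 0.0211) rose more in Dbp2-FRB-GFP cells, and ASP3-1 had an interaction of −1.91 ± 0.33 (0.0211). The snR56 density was 2.27 in untreated and 2.43 in treated parental cells. YCR081C-A (1.64 ± 0.32, 0.0593) and DBP2 (0.26 ± 0.23, 0.637) were not called. Limma called 0 XUTs of 1461, with 163 at an unadjusted p under 0.05 against 73.05 by chance, 14 adjusted over the list alone, and 2 by voom. It called 0 CUTs (119 at an unadjusted p under 0.05), 1 NUT, 1 snoRNA and 2 protein-coding features, 1 of them lower. NUT0013 and snR56 also moved alike in tagged against parental cells without rapamycin (1.90 and 1.83). The file does not show whether the 2 share reads, so they may not be separate results. The median interaction was 0.20 for XUTs, 0.20 for CUTs, 0.17 for NUTs, 0.03 for snoRNAs and 0.23 for protein-coding features. After scaling to protein-coding features or quantile normalization 0 features were called, with snR56 at 0.98 (adjusted p = 0.135) and 1.11 (0.0606), NUT0013 at 0.93 (0.266) and 0.97 (0.256), RRT5 at 1.73 (0.378) and 1.74 (0.372) and ASP3-1 at −1.97 (0.266) and −2.14 (0.291). At unchanged values, snR56, NUT0013 and RRT5 were lost without a trend (0.0717) and NUT0013 (0.0972), RRT5 (0.124) and ASP3-1 (0.112) without a filter, and with a pseudocount at the 1st percentile RRT5 was lost at 2.25 (0.0882). Other settings called more: 49 features and 15 XUTs after scaling to snoRNAs and 73 and 24 with a filter at the 25th percentile. A pseudocount at the 25th percentile gave 9 and 2. With the replicate number as a block 101 and 34 were called, and whether same-numbered samples were paired is not settled here.

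Of the lists limma called 0 members of each, with 935 of 9656 features at an unadjusted p under 0.05 and 16 called by voom. Adjusted over the list alone 7 histone genes, 1 α-specific gene and 1 gene of the other mating type were called. HHT1 was at 0.67 ± 0.19 (adjusted p = 0.207, and 0.0184 without Dbp2-FRB-GFP rapamycin replicate 2). Camera called histones higher (2.1e-04) and nitrogen (0.019) and α-specific genes (9.6e-06) lower, with adjusted p of 0.974, 0.974 and 0.706 with an estimated correlation, and did not call the other lists (0.0561 to 0.94). Among the classes it called protein-coding features higher (2e-04) and snoRNAs (2.8e-05), NUTs (0.0017), XUTs (0.025), CUTs (0.025) and mitochondrial features (0.023) lower than other features, and none held with an estimated correlation (adjusted p = 0.607 to 0.618). Fry called no class (0.247 to 0.556) and no list (0.531 to 0.803). RRT5 was lost without parental untreated replicate 2 (1.68, 0.116) and ASP3-1 without parental untreated replicate 1 (−1.75, 0.0871), and YCR081C-A was called (0.00377 to 0.0185) without any 1 of 5 libraries. The counts without 1 library were 10 and 8 (parental untreated replicates 1 and 2), 80 and 126 (parental rapamycin), 73 and 64 (Dbp2-FRB-GFP untreated) and 58 and 62 (Dbp2-FRB-GFP rapamycin), and for XUTs 2, 1, 28, 44, 26, 18, 15 and 13.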

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

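Of the tests in this part, those of the spike-in ratio, of a single scaling factor and of the other α-specific genes were chosen only after the result was seen, and the requirement that both neighbour comparisons lie under the bound was added after their values were known.

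The interaction test called 4 features on the spike-in scale. It was 1.232 for snR56 and 1.183 for NUT0013, 2.013 for RRT5 and −1.911 for ASP3-1 on the log2 scale. Whether snR56 and NUT0013, which have similar numbers of reads, share reads is not shown by the file. ASP3-1 had 5 to 57 reads and near-identical copies. All 4 calls ended after scaling to protein-coding features or quantile normalization (snR56 at 0.98 and 1.11, adjusted p = 0.135 and 0.0606; NUT0013 at 0.93 and 0.97, RRT5 at 1.73 and 1.74 and ASP3-1 at −1.97 and −2.14, adjusted p = 0.256 to 0.378). Also lost were those of snR56, NUT0013 and RRT5 without a trend (0.0717), those of NUT0013, RRT5 and ASP3-1 without a filter (0.0972 to 0.124), that of RRT5 with a pseudocount at the 1st percentile (0.0882), and those of RRT5 and ASP3-1 without 1 library (parental untreated replicate 2, 1.68, 0.116, and replicate 1, −1.75, 0.0871). The values kept their direction in each of these, and without a trend or filter they are the same, so the lost calls alone do not show that the differences rest on the scale.

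Protein-coding features were higher in Dbp2-FRB-GFP cells on the spike-in scale, at a level of 1.01 against 0.846 without rapamycin and 1.30 against 0.909 with it. A different ratio of spike-in to yeast RNA between libraries, for example from the amount of RNA at the time of spiking, would raise every class, and the lowest class median over both strain comparisons was 0.257, above 0. This explanation and a rise of yeast RNA per cell cannot be told apart, because the step at which spike-ins were added is not given in the sources used here. In treated against untreated Dbp2-FRB-GFP cells, snoRNAs stood at 1.26 and 1.26 while protein-coding features went from 1.01 to 1.30. In these means 1 factor per library would have moved both. But treated replicates 1 and 2 were at 1.397 and 1.194 for protein-coding features and at 1.193 and 1.318 for snoRNAs. The classes thus differed in opposite directions between replicates, so the group means carry little weight here. An effect of the tag or strain stays open, untested.

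CUTs rose more than protein-coding features in the tagged strain. With 1 scaling factor per library as the cause, the CUT median would lie near 0 after scaling to protein-coding features, but it was 0.63 without and 0.594 with rapamycin. These values restate the difference between the classes, which 1 factor per library cannot make, and are no separate test. Lower levels and shorter lengths of CUTs as the whole cause are argued against too: CUTs lay 0.336 (95% interval 0.297 to 0.381) and 0.314 (0.276 to 0.364) above protein-coding features matched on mean density and length, though matching lowered the difference from 0.577 and 0.526. The excess may be biological, from the tag, the strain or its growth, which the design does not separate, and the camera call of CUTs was lost with an estimated correlation (adjusted p = 0.175 and 0.45).

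Low open reading frames just behind highly expressed genes, such as YMR230W-A, YBR032W and RRT5, were among the features that rose most. Features with a convergent neighbour lay −0.062 from features with a same-strand downstream neighbour in the strain comparison where the difference was highest. This cannot decide whether reads of a neighbour were counted whatever the strand, because such reads, counted in both strains, need not raise a fold change. Transcripts running on from the upstream gene on the same strand could explain the pattern: such features lay 0.026 (95% interval −0.09 to 0.12) above those with a divergent upstream neighbour without rapamycin and 0.109 (0.004 to 0.22; permutation p = 0.0587, adjusted p = 0.238 over 6 tests) with it, in 168 and 98 features. Without rapamycin the interval lies below 0.2, the size set beforehand for this explanation. That argues against a rise of this size in the typical feature of the set there. A median cannot show run-on in a minority of the features. The interval with rapamycin holds both values near 0 and that size, so run-on stays open with rapamycin and for single features such as YMR230W-A.

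MF(ALPHA)2 fell 10-fold in the tagged strain while MF(ALPHA)1, STE3 and SAG1 had a median of −0.123 on the spike-in scale, far from the fall that cells of another mating type would give all of them.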

How the results depend on the processing

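Tests on voom, on at least 50 mean reads and with an estimated correlation after scaling to protein-coding features were chosen only after the result was seen. Values are called features, then XUTs, unless classes or lists are named, and the cause of a difference was not tested except where fewer features or samples entered. Comparisons are written R-par (rapamycin in parental cells), tag, R-tag (rapamycin in Dbp2-FRB-GFP cells), strains-R (strains with rapamycin) and interaction.

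Main counts were 3 and 2 (R-par), 4485 and 828 (tag), 1336 and 144 (R-tag), 7009 and 1102 (strains-R) and 4 and 0 (interaction). With a log2 fold change of at least 1: tag 999 and 256, R-tag 44 and 13, strains-R 1957 and 485. With at least 50 mean reads: R-par 1 and 0, tag 2672 and 270, R-tag 52 XUTs, strains-R 346 XUTs. A pseudocount at the 25th percentile gave R-par 8, R-tag 2154 and 256, interaction 9 and 2 with 5 lists. No filter gave R-par 0 and 0, R-tag 279 and 30, interaction 1. A filter at the 25th percentile gave R-par 61 and 12, R-tag 2538, interaction 73 and 24 with 7 lists. Scaling to protein-coding features gave R-par 0 and 0 with 2 classes, R-tag 18 and 0 with 2 classes, strains-R 611 XUTs with 5 classes, interaction 0 with 2 classes and 9 lists. Scaling to snoRNAs gave R-par 47 and 16 with 2 classes, tag 2617 and 329, R-tag 185 and 40, strains-R 2244 and 439 with 11 lists, interaction 49 and 15. Quantile normalization gave R-par 0 and 0 with 2 classes, tag 400 XUTs with 3 classes, R-tag 5 and 0 with 1 class, strains-R 4205 and 479, interaction 0 with 1 class and 6 lists. Without a trend R-tag had 209 and 43. Voom gave R-par 23, R-tag 3008 and 263, interaction 16 and 2 with 5 lists. Fitting only the groups compared gave R-par 64 and 15 and R-tag 252 XUTs. XUTs adjusted over the class alone were 8 in R-par, 92 in R-tag and 14 in the interaction. With an estimated correlation 0 classes and 0 lists were called in any comparison, and after scaling to protein-coding features 1 class in tag and 1 in strains-R.

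With the replicate number as a block, R-par had 57 and 16 with 2 classes and the interaction 101 and 34 with 5 lists, against 4240 and 843 (tag), 904 and 153 (R-tag) and 6793 and 1119 (strains-R). Deviations of same-numbered libraries correlated at −0.134 to 0.151, so no strong shared effect of the number was seen. Weak correlations cannot settle whether same-numbered samples were paired.

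Leaving out 1 library gave R-par 1 to 77 features, 0 to 25 XUTs, 0 to 6 classes and 3 to 10 lists; tag 2733 to 4983, 566 to 877, 3 to 5 and 6 to 8; R-tag 117 to 4712, 24 to 379, 4 to 5 and 6 to 9; strains-R 5534 to 7388, 913 to 1114, 1 to 4 and 7 to 9; interaction 8 to 126, 1 to 44, 0 to 6 and 4 to 7. Sign changes were counted only for named values called in the main test or in the alternative. Of these, 5 changed sign after scaling to snoRNAs: CYB5 (−0.20), RPC19 (−0.24), STE2 (−0.0199) and MF(ALPHA)1 (−0.45) in tag and DBP2 (−0.14) in strains-R. MF(ALPHA)1 also did after quantile normalization (−0.20); not called in the main test, it was called lower with both (adjusted p = 0.0343 and 0.0263). On simulated data features under 50 reads made up 99.5% (strains-R) and 100% (interaction) of the false calls with library-wide shifts, and 75 and 51.5% without.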

Other observations

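Of the tests in this part, that of genes attenuated by Nrd1, Nab3 and Sen1 and that of features behind snoRNAs were chosen only after the result was seen; the lists were written after the genes named as seen earlier.

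GTT2, OYE3 and YNL134C, which fell in the tagged strain, are known targets of Yap1, the transcription factor of the response to oxidants and electrophiles. Of 24 other Yap1 targets tested, 10 were lower and 1 higher without rapamycin, with a median log2 fold change of −0.16 against 0.26 for protein-coding features. None of 10000 random lists of the same size and matched expression had a median as low (percentile 0). Random lists were drawn gene by gene and do not allow for genes that vary together, so this percentile overstates the support. Camera with an estimated correlation was not run on this list. With rapamycin 10 were lower and 6 higher, with a median of 0.03 against 0.50. The median lay −0.419 from that of protein-coding features in the comparison where it was closest. A lower activity of part of the Yap1 regulon in the tagged strain is a hypothesis. Lower targets without rapamycin included the drug exporters ATR1 (−1.60) and FLR1 (−0.73) and the glutathione synthesis gene GSH1 (−1.21). AAD6 (−1.56), AAD4 (−1.05), GRE2 (−0.91) and the vacuolar transporter YCF1 (−0.68) were also lower, while the catalase CTA1 was at 1.18. Not called were TRX2 (−0.13), TRR1 (−0.19), GLR1 (−0.13), AHP1 (0.05), TSA1 (0.15) and GPX2 (0.14). With rapamycin TSA1 (0.42) and GPX2 (0.60) were called higher. The reference annotates AAD6 as a pseudogene. AAD genes have close paralogs, so their reads are uncertain. Whether the tag or an unrelated difference between the strains underlies it was not tested.

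Noncoding classes lay above protein-coding features of matched density and length by less than their unmatched difference. XUTs lay 0.084 (95% interval 0.06 to 0.11) above without rapamycin and 0.067 (0.037 to 0.109) with it, against 0.286 and 0.253 unmatched, and NUTs 0.162 and 0.115. In parental cells the XUT difference with rapamycin was −0.009 (−0.02 to 0.003). Only 16 of 76 snoRNAs found a match, so that check is void for snoRNAs.

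NRD1 rose in the tagged strain, and its own transcript is attenuated by the Nrd1, Nab3 and Sen1 complex. Weaker early termination would raise other such genes. Of 8 tested, NRD1 among them, 2 were higher and 2 lower without rapamycin and 3 and 2 with it, and their median lay −0.456 from that of protein-coding features in the comparison where it was closest. Without NRD1, HRP1 and PCF11, which were seen first, the 5 others had medians of −0.27 against 0.26 without and −0.25 against 0.50 with rapamycin and 0 called higher, the opposite of the prediction. That part leaves out genes called higher, and over the whole list the calls went both ways, so the explanation stays open. snoRNA transcripts running on into the gene behind them would raise those genes, but 21 features within 500 nt behind a snoRNA lay −0.043 (95% interval −0.119 to 0.086) from protein-coding features. These 21 were taken at any expression level. Added reads could go unseen in highly expressed genes, so run-on is not excluded.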
